A study of Mus musculus with 12 samples.

How the data were processed

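RNA was measured by bulk sequencing in 12 libraries from cells labelled as naive CD4 T cells from the spleen of C57BL/6 mice, either wild type (WT) or without TNF receptor 2 (Tnfr2-/-, gene Tnfrsf1b). Per the labels' protocols, 500000 cells per well were activated for 3 days on plates coated with antibodies to CD3 and CD28 at 2 μg/ml each. Where cytokines were added, IL-6 or TNF was used at 20 ng/ml and TGF-β at 2 ng/ml. The 4 groups of 3 libraries were WT without added cytokine (Th0), WT with IL-6+TGF-β, WT with TNF+TGF-β and Tnfr2-/- with TNF+TGF-β. The labels call the samples of a group triplicates and do not say whether they came from separate mice or cultures. The p-values therefore measure only the spread between these samples, which may be technical. Per the labels' protocols, cDNA was made with a SMARTer ultra low input kit and libraries with Nextera XT. That library kit does not mark the strand, so reads of overlapping or antisense genes could not be told apart.

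Per the submitters' processing notes, Trimmomatic (version not given in the sources used here), STAR 2.5.4 and RSEM 1.3.1 were used with the mouse genome mm10. The deposited table held 1 value per gene and library for 47643 genes, and per the file headers these were gene-level RSEM results with no pooling of replicates. The headers did not say which RSEM quantity had been kept. The values were read as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library) made by the authors, because the sums differed between libraries, from 689045 to 828161. Each value multiplied by the gene's mean transcript length in kilobases summed to between 900467 and 1010096 per library, close to the fixed total that FPKM give. The design fixed beforehand had assumed estimated counts from the same program, and its stated fallback for FPKM was used in place of the count model. The gene annotation used by the authors was not given in the sources used here. Of the gene identifiers, 47224 (99.1%) were found in GENCODE M21 (GRCm38), from which coordinates were taken, and 708 had no symbol in the table. The value was 0 in all 12 libraries for 49.5% of the genes. The column names of the Tnfr2-/- group carried the numbers 1, 2 and 4, while its labels carried 1, 2 and 3. The column numbered 4 was therefore used as a member of its group, not tied to a single label, and is called the library numbered 4.

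Depth was not given. It was estimated from the steps between low FPKM values of 8037 genes with a single transcript of 800 to 3000 bases, after 300 bases were subtracted from each length. Between 84.4% and 92.3% of those values lay within 0.2 of a whole multiple of the estimated step. The estimates ran from 16700000 fragments in the Tnfr2-/- library numbered 4 to 24000000 in replicate 2 of IL-6+TGF-β. The subtraction was the one that fitted best among several, the method was chosen after the data had been seen, and the estimates are approximate. At that depth, 3 fragments on a transcript of 1 kilobase corresponded to 0.125 to 0.179 FPKM, so lower values of short genes rest on a few fragments. This limit covers counting error only.

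Genes with at least 1 FPKM in at least 3 libraries were tested, which left 13082. Values were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 libraries, no covariate, and a variance prior that followed the mean level. Each fold change is on this log2(FPKM + 1) scale, which understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method over all tested genes within each of the 4 comparisons. A gene is called higher or lower at an adjusted p under 0.05. The comparisons were TNF+TGF-β against Th0, IL-6+TGF-β against Th0 and TNF+TGF-β against IL-6+TGF-β, all in WT, and Tnfr2-/- against WT under TNF+TGF-β. No Tnfr2-/- Th0 group was analysed here, so an effect of genotype without cytokines was not separated. No group with TGF-β alone was analysed either, so effects of TNF or IL-6 were not separated from those of TGF-β.

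The groups, tests, gene lists, named genes and alternatives were chosen before the data were examined, except those named below as added. The text names 13 of 14 fixed genes, the 6 largest rises and 6 largest falls per comparison, and up to 3 called members of each gene list by size of change. The largest changes were taken among called genes with at least a 2-fold change, a mean of at least 10 FPKM in the higher group, and no overlap between the libraries of both groups. Predicted genes and immune receptor segments were left out of these. Any other gene is said to have been chosen after its values were seen. The 23 lists covered T helper programs, signalling responses, cytokines and receptors of the TNF family, cell cycle, metabolism, and markers of B, myeloid, dendritic, CD8 and NK, and erythroid cells. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 23 lists. Counts of called members were also made with p-values adjusted over the list alone. Of 92 list tests, 40 passed with the preset correlation, and 3 of these held with an estimated one. Those 3 were the Th17 list and the IL-6 and STAT3 list with IL-6+TGF-β against Th0, and the IL-6 and STAT3 list between the cytokine pairs.

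The same code was tested on simulated libraries with the real means and spread of the 13082 genes, of which 66 or 67 of the more highly expressed were changed per fold and comparison. Of genes changed 4-fold, 97.0%, 92.4%, 92.4% and 100% were found for the comparisons in the order given above. Of genes changed 2-fold, 56.7%, 59.7%, 64.2% and 55.2% were found, and of genes changed 1.5-fold, 20.9%, 32.8%, 29.9% and 22.4%. The unchanged share of all calls was 2.5%, 8.2%, 3.9% and 2.5%.

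The alternatives chosen beforehand were median-ratio and upper-quartile scaling, no filter, a stricter filter, a fit of only the groups compared, a replicate block, a test against a 1.5-fold change with limma's treat, and leaving out each library. Added after the data had been seen were a pseudocount of 0.1, rescaling to TPM, scaling to 18 T cell core genes, and the Tnfr2-/- comparison without marker genes of other cells. The count models of the design were not run, since no counts were used. No columns of other samples were in the table. Overlapping annotated genes were listed for Foxp3, Il2ra, Csf2, Ifng, Gata3 and Il2, and near-identical copies (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Hspa1a and Hspa1b, Bcl2a1b and Bcl2a1d) are uncertain, since the program can divide shared reads between them.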

Results

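RNA was sequenced in 12 libraries from mouse spleen cells labelled as CD4 T cells, 3 days after activation through CD3 and CD28. In 11 of the 12 libraries Cd8a and Cd8b1 were both above Cd4, and markers of B cells were also present. WT cells received no added cytokine (Th0), IL-6+TGF-β or TNF+TGF-β, and cells without TNF receptor 2 (TNFR2) received TNF+TGF-β, with 3 libraries per group. TGF-β with IL-6 is the standard way to make Th17 cells, and TGF-β without IL-6 favours regulatory T (Treg) cells. The comparisons asked which genes each cytokine pair changed, where the pairs differed, and which genes differed without TNFR2. Estimated depth was 16700000 to 24000000 fragments per library, and 13082 genes were tested. Rank correlations (Spearman, across genes, which are not independent replicates) were 0.95 to 0.982 within groups and 0.865 to 0.947 between groups. On the first principal component, 32.1% of the variance, the Tnfr2-/- libraries lay at 42.73 to 79.22 and all WT libraries below 0.

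The gene removed in the Tnfr2-/- mice is Tnfrsf1b (ENSMUSG00000028599.10), which lies on chromosome 4 at 145213463 to 145246870 of GRCm38. Its values were 17.39, 22.56 and 18.44 FPKM in the Th0 libraries, 36.66, 77.43 and 64.85 with IL-6+TGF-β, and 74.39, 108.17 and 70.77 with TNF+TGF-β. In the Tnfr2-/- libraries it was listed at 4.87, 3.71 and 3.19 FPKM. Tnfrsf1b rose with TNF+TGF-β against Th0 (log2 difference 2.04, adjusted p = 0.000111) and fell in Tnfr2-/- cells (−4.11, adjusted p = 1.17e-06). The values are sums over the whole gene, so the remaining Tnfr2-/- signal could not be placed on particular exons. Tnfrsf1a (ENSMUSG00000030341.17, chromosome 6, 125349362 to 125362484) encodes the other TNF receptor, TNFR1. It rose from 11.4 ± 2.38 FPKM in Th0 to 27.3 ± 3.55 with TNF+TGF-β (SD, n = 3 each; adjusted p = 0.000605) and was 14.4 ± 3.47 in Tnfr2-/- cells (adjusted p = 0.00357 against WT).

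**Figure D1:**
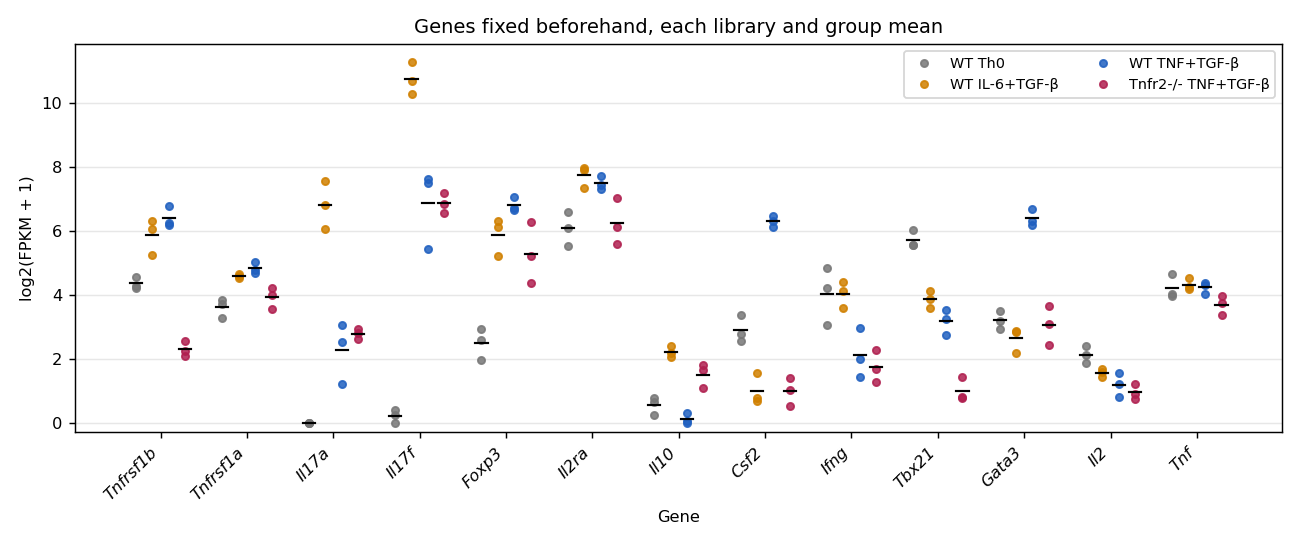
Expression of 13 fixed genes in each library, as log2(FPKM + 1), with 1 point per library, 4 groups of 3 libraries and black bars at group means. Csf2 and Gata3 were high with TNF+TGF-β in WT cells alone, and Il17a was highest with IL-6+TGF-β.

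Other fixed genes were located in the same annotation. The cytokine genes Il17a (ENSMUSG00000025929.4, 20730905 to 20734496) and Il17f (ENSMUSG00000041872.9, 20777146 to 20790617) are neighbours on chromosome 1, which also carries Il10 (ENSMUSG00000016529.5, 131019845 to 131024974). Il2 (ENSMUSG00000027720.7, 37120523 to 37125959) lies on chromosome 3. Il2ra (ENSMUSG00000026770.5, 11642807 to 11693193) and Gata3 (ENSMUSG00000015619.10, 9857078 to 9890034) lie on chromosome 2. Csf2 (ENSMUSG00000018916.5, 54247271 to 54249667) and Tbx21 (ENSMUSG00000001444.2, 97098071 to 97115331) lie on chromosome 11. Foxp3 (ENSMUSG00000039521.12, 7573644 to 7595245) is on the X chromosome, Ifng (ENSMUSG00000055170.3, 118441046 to 118445892) on chromosome 10, and Tnf (ENSMUSG00000024401.14, 35199381 to 35202007) on chromosome 17.

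TNF+TGF-β raised genes of both the Th17 and the Treg programs over Th0. Foxp3, which encodes the Treg transcription factor, rose from 4.82 ± 1.86 to 112 ± 17.8 FPKM (SD, n = 3 each; log2 difference 4.32 ± 0.43 (SE), adjusted p = 1.47e-05). Itgae, which encodes the integrin chain CD103, had the largest rise, from 0.507 ± 0.105 to 345 ± 108 FPKM. Il17f rose from 0.157 ± 0.150 to 139 ± 84.6 FPKM, while Il17a was listed at 0 in every Th0 library and at 7.36, 1.3 and 4.67 FPKM with TNF+TGF-β (adjusted p = 0.002). Gata3, the Th2 transcription factor gene, rose from 8.28 ± 1.85 to 83.2 ± 15.1 FPKM, and Csf2, which encodes GM-CSF, rose from 6.62 ± 2.33 to 77.4 ± 8.73. Tbx21, which encodes the Th1 factor T-bet, fell from 52.1 ± 10.3 to 8.18 ± 2.36 FPKM, Ifng fell from 17.5 ± 10.2 to 3.82 ± 2.64, and Il2 fell from 3.40 ± 0.81 to 1.32 ± 0.59. Il2ra, the high-affinity IL-2 receptor gene, rose from 69.4 ± 25.3 to 178 ± 25.02 FPKM (adjusted p = 0.00857). Tnf itself was 17.9 ± 5.36 FPKM in Th0 and 17.9 ± 2.36 with TNF+TGF-β, and Il10 was 0.487 ± 0.265 against 0.0867 ± 0.1172 FPKM (adjusted p = 0.153), which passed as a fall only with a pseudocount of 0.1 (adjusted p = 0.0301).

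Of the Th17 list, 11 of 16 tested genes were higher and 0 lower with TNF+TGF-β than in Th0 (11 higher and 1 lower adjusted over the list alone; list test adjusted p = 5.53e-07, adjusted p = 0.0687 with an estimated correlation). They included Ccl20, a chemokine gene of Th17 cells, at 104 ± 49.97 against 3.54 ± 2.68 FPKM, and Maf, a transcription factor gene, at 13.8 ± 1.15 against 0.99 ± 0.44. In the Treg list 10 of 18 genes were higher and 2 lower (12 and 3 adjusted over the list alone; adjusted p = 0.00296, adjusted p = 0.313 with an estimated correlation), with Ikzf4 at 44.99 ± 10.4 against 1.51 ± 1.19 FPKM and Tigit, a coinhibitory receptor gene, falling from 37.9 ± 4.79 to 7.82 ± 1.38. The TGF-β and SMAD list had 12 of 13 genes higher and 0 lower (12 adjusted over the list alone; adjusted p = 4.83e-09, adjusted p = 0.172 with an estimated correlation). Its members Ldlrad4 and Tgfbr1, an inhibitor and a receptor of the TGF-β pathway, rose by 4.36 and 3.91 log2 units. Of the list of TNF superfamily receptors and ligands, 10 of 19 genes were higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 0.000111, adjusted p = 0.270 with an estimated correlation). Tnfrsf25, the receptor gene DR3, rose from 2.17 ± 0.89 to 54.4 ± 6.28 FPKM, and Cd70, the ligand gene of CD27, from 3.68 ± 0.26 to 44.8 ± 4.27. In the NF-κB and TNF list 8 of 20 genes were higher and 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.0215, adjusted p = 0.348 with an estimated correlation), among them the feedback inhibitors Tnfaip3, from 14.1 ± 5.11 to 56.3 ± 19.4 FPKM, and Tnip1, from 26.0 ± 6.78 to 98.0 ± 21.3.

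Interferon-response and glycolysis genes fell with TNF+TGF-β. In the type I interferon list 14 of 18 genes were lower and 0 higher (15 lower adjusted over the list alone; adjusted p = 4.83e-09, adjusted p = 0.172 with an estimated correlation), with Zbp1, a nucleic acid sensor gene, at 18.2 ± 1.69 against 164 ± 21.4 FPKM in Th0. Of the glycolysis list, 14 of 17 genes were lower and 0 higher (15 lower adjusted over the list alone; adjusted p = 9.63e-08, adjusted p = 0.270 with an estimated correlation), among them Aldoa, which encodes aldolase, at 554 ± 61.5 against 1407 ± 43.5 FPKM. The largest falls included Gzmb, the granzyme B gene, from 318 ± 263 to 1.497 ± 0.612 FPKM, Ly6a, which encodes the surface protein Sca-1, from 1371 ± 140 to 21.1 ± 0.94, and Iigp1, an interferon-induced GTPase gene, from 69.1 ± 1.33 to 0.863 ± 0.218. In the Th1 and cytotoxic list 7 of 17 genes were lower and 3 higher (8 and 3 adjusted over the list alone), the higher ones including Il18rap, a chain of the IL-18 receptor, at 23.0 ± 2.495 against 3.41 ± 0.42 FPKM. In the Th2 and Th9 list 4 of 8 genes were higher and 1 lower (the same counts adjusted over the list alone), with the chemokine receptor gene Ccr8 at 520 ± 27.9 against 18.5 ± 1.41 FPKM. Of the 28 cell cycle genes, 3 were lower and 0 higher, and 0 adjusted over the list alone, with a median difference of −0.09 that turned to 0.09 under TPM. The tests of the Th1 and cytotoxic, the Th2 and Th9, and the cell cycle lists did not pass (adjusted p = 0.081, 0.081 and 0.225).

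Marker genes of other cells changed between these groups too. All 8 B cell markers were lower with TNF+TGF-β than in Th0 (8 adjusted over the list alone; adjusted p = 1.66e-05, adjusted p = 0.302 with an estimated correlation), with Cd79a, a B cell receptor signalling chain gene, at 92.6 ± 26.6 against 296 ± 48.1 FPKM. Of the MHC class II and dendritic cell list, 4 of 6 genes were lower and 2 higher (4 and 2 adjusted over the list alone), with H2-Ab1 at 393 ± 95.9 against 1414 ± 317. The test of that list did not pass (adjusted p = 0.194). Cd8a, a chain of the CD8 coreceptor, was 173 ± 22.1 against 60.5 ± 12.9 FPKM (adjusted p = 0.0072).

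Over all genes, 2442 were higher and 1703 lower with TNF+TGF-β than in Th0, or 58.9% higher, and 1081 and 618 of them changed at least 2-fold. Rescaled to TPM, 3277 were higher and 1243 lower, or 72.5% higher, and the median shifted by 0.154. Median-ratio scaling gave 2134 higher and 2185 lower, or 49.4% higher, so the excess of rises depended on the scaling. The number lower depended on single libraries, being 1111 without Th0 replicate 1, 1106 without Th0 replicate 3 and 1101 without TNF+TGF-β replicate 2. No overlap between the libraries of both groups was seen for 55.1% of genes, against 10% by chance. Other large rises were those of Nupr1, a stress-response gene, from 0.54 ± 0.57 to 194 ± 32.2 FPKM, and Fbxo2, a ubiquitin ligase adaptor gene, from 0.35 ± 0.10 to 81.7 ± 6.93.

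With IL-6+TGF-β both interleukin-17 genes were among the largest rises. Il17f rose from 0.157 ± 0.150 FPKM in Th0 to 1777 ± 633 (SD, n = 3 each; adjusted p = 3.36e-08). Il17a was listed at 0 in every Th0 library and at 186.24, 65.16 and 111.14 FPKM with IL-6+TGF-β (adjusted p = 4.22e-07). Il21, another cytokine gene of Th17 and follicular helper cells, was likewise at 0 in Th0 and at 10.8 ± 1.00 FPKM with IL-6+TGF-β (adjusted p = 1.31e-08). Foxp3 also rose, from 4.82 ± 1.86 to 60.4 ± 21.7 FPKM. Socs3, a feedback inhibitor of the IL-6 receptor and a STAT3 target, rose from 5.01 ± 1.92 to 138 ± 11.9 FPKM. Il10 rose from 0.487 ± 0.265 to 3.63 ± 0.61 FPKM and Il2ra from 69.4 ± 25.3 to 215 ± 46.6, while Csf2 fell from 6.62 ± 2.33 to 1.06 ± 0.73 and Tbx21 from 52.1 ± 10.3 to 13.7 ± 2.65. Gata3 was 5.34 ± 1.55 against 8.28 ± 1.85 FPKM (adjusted p = 0.2004), and Ifng was 15.8 ± 4.65 against 17.5 ± 10.2 (adjusted p = 0.999).

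The Th17 list had 14 of 16 genes higher and 0 lower with IL-6+TGF-β than in Th0 (14 adjusted over the list alone; adjusted p = 5.66e-13, adjusted p = 0.00735 with an estimated correlation). In the IL-6 and STAT3 list 11 of 14 genes were higher and 0 lower (11 adjusted over the list alone; adjusted p = 2.13e-08, adjusted p = 0.0105 with an estimated correlation), with Bcl3, an NF-κB cofactor gene, at 186 ± 6.51 against 29.1 ± 5.68 FPKM. The TGF-β and SMAD list had 12 of 13 genes higher and 0 lower (13 adjusted over the list alone; adjusted p = 4.42e-10, adjusted p = 0.0861 with an estimated correlation), among them Pmepa1, a TGF-β feedback gene, at 77.0 ± 8.99 against 5.36 ± 1.74. In the type I interferon list 16 of 18 genes were lower and 0 higher (17 lower adjusted over the list alone; adjusted p = 8.92e-12, adjusted p = 0.0762 with an estimated correlation), including the RNA sensor gene Ifih1 at 1.07 ± 0.09 against 16.5 ± 0.67 FPKM. Of the coinhibitory receptors 5 of 10 were lower and 1 higher (5 and 1 adjusted over the list alone; adjusted p = 0.00401, adjusted p = 0.0742 with an estimated correlation), and Cd200 fell from 528 ± 43.0 to 30.5 ± 4.02 FPKM. In the list of T cell cytokines 10 of 19 genes were higher and 2 lower (10 and 4 adjusted over the list alone; adjusted p = 0.00373, adjusted p = 0.307 with an estimated correlation). Of the naive T cell list 6 of 13 genes were higher and 2 lower (6 and 2 adjusted over the list alone), among them Il7r, the IL-7 receptor gene, at 20.98 ± 4.39 against 0.967 ± 0.459 FPKM, and S1pr1, which guides exit from lymphoid organs, at 81.8 ± 18.2 against 21.5 ± 5.97. The AP-1 and stress list had 3 of 13 genes higher and 1 lower (3 and 1 adjusted over the list alone), with Jun at 94.6 ± 11.1 against 18.8 ± 3.02 FPKM. The tests of the naive T cell list and of the AP-1 and stress list did not pass (adjusted p = 0.0586 and 0.794).

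Other large rises with IL-6+TGF-β were those of Timp1, a metalloproteinase inhibitor gene, from 0.67 ± 0.30 to 249 ± 79.9 FPKM, and Aqp3, a water and glycerol channel gene, from 2.64 ± 0.47 to 428 ± 8.78. Serpina3f, a protease inhibitor gene induced by interferon, fell from 100 ± 11.4 to 0.343 ± 0.171 FPKM. Of markers of other cells, 2 of 8 B cell genes were lower and 0 higher (4 lower adjusted over the list alone), as were 3 of 6 of the MHC class II and dendritic cell list (5 lower adjusted over the list alone). The B cell list test did not pass (adjusted p = 0.097). Of the CD8 and NK list 3 of 5 genes were higher and 0 lower (3 adjusted over the list alone). In the myeloid list 4 of 13 genes were lower and 0 higher (5 lower adjusted over the list alone), among them Mpeg1, a macrophage pore-forming protein gene, at 0.617 ± 0.245 against 12.7 ± 3.26 FPKM. Klrd1, which encodes the NK receptor chain CD94, rose from 16.2 ± 6.57 to 165 ± 17.7 FPKM. Over all genes, 1844 were higher and 1197 lower, or 60.6% higher, and 863 and 547 changed at least 2-fold. The share higher was 52.8% under median-ratio (1681 and 1501) and upper-quartile scaling (1677 and 1501), and 69.5% under TPM (2221 and 973). Without Th0 replicate 3 the number lower was 790. No overlap was seen for 39.2% of genes, against 10% by chance.

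**Figure D2:**
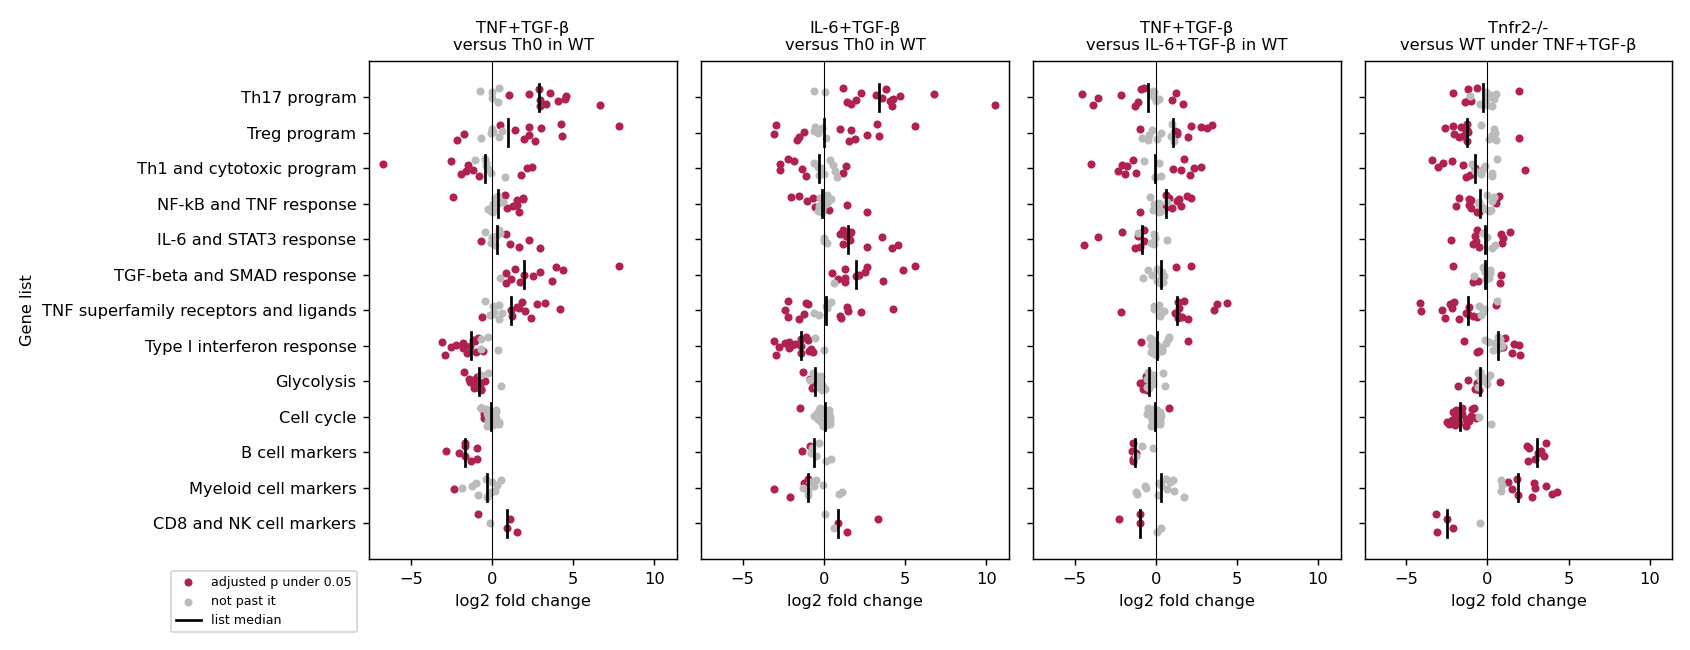
Log2 difference of each tested member of 13 gene lists in the 4 comparisons, with 1 point per gene, red at an adjusted p under 0.05, grey otherwise, and black bars at list medians. Th17 genes had medians of 2.91 and 3.37 against Th0, and cell cycle genes a median of −1.71 in Tnfr2-/- against WT cells.

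Both cytokine pairs changed many of the same genes against Th0. Called higher with both were 1202 genes, 49.2% of those higher with TNF+TGF-β, and called lower with both were 782, or 45.9%. Independent calls would have shared 344.2 and 155.8. Foxp3, Itgae and Ccl20 were among the shared rises and Tbx21, Serpina3f and Iigp1 among the shared falls. The Th0 libraries served in both comparisons and were too few to be divided between them, so part of the excess may come from shared libraries. Simulated data without effects, in which genes varied independently, gave a correlation of 0.5 across genes against the measured 0.687. They gave a covariance of 0.046 against 0.452, and at most 1 shared call. Without Th0 replicate 3 the shared calls fell from 1984 to 1318. Called in opposite directions were 73 genes, Csf2 and Cd70 among them.

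Between the cytokine pairs, the interleukin-17 genes were lower with TNF+TGF-β than with IL-6+TGF-β, and Csf2 and Gata3 higher. Il17a was 4.44 ± 3.04 FPKM with TNF+TGF-β against 121 ± 61.1 with IL-6+TGF-β (SD, n = 3 each; log2 difference −4.55 ± 0.43 (SE), adjusted p = 1.85e-05), and Il17f was 139 ± 84.6 against 1777 ± 633 (−3.88 ± 0.47, adjusted p = 0.000144). Csf2 was 77.4 ± 8.73 against 1.06 ± 0.73 FPKM (5.30 ± 0.29, adjusted p = 3.30e-07), and Gata3 was 83.2 ± 15.1 against 5.34 ± 1.55 (3.75 ± 0.30, adjusted p = 4.71e-06). Il10 was lower with TNF+TGF-β, at 0.0867 ± 0.1172 against 3.63 ± 0.61 FPKM. Foxp3 was 112 ± 17.8 against 60.4 ± 21.7 FPKM (adjusted p = 0.195), and Tnfrsf1b was 84.4 ± 20.6 against 59.7 ± 20.9 (adjusted p = 0.227). Ccl22, a chemokine gene whose product attracts Treg and Th2 cells, was 35.6 ± 5.01 against 0.0867 ± 0.0777 FPKM, and Il1r2, a decoy receptor gene for IL-1, was 102 ± 43.2 against 2.84 ± 0.18. Gpr15, a gut-homing receptor gene, was 1.60 ± 0.36 against 84.8 ± 4.11 FPKM, and Socs3 was 5.80 ± 2.01 against 138 ± 11.9.

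Of the TNF superfamily list, 11 of 19 genes were higher and 1 lower with TNF+TGF-β than with IL-6+TGF-β (11 and 1 adjusted over the list alone; adjusted p = 4.81e-08, adjusted p = 0.156 with an estimated correlation). Cd70 was 44.8 ± 4.27 against 1.17 ± 0.34 FPKM, Tnfsf11, which encodes RANKL, 126 ± 12.4 against 8.37 ± 1.08, and Tnfsf8, which encodes CD30L, 64.7 ± 9.09 against 4.49 ± 0.57. In the NF-κB and TNF list 10 of 20 genes were higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 0.000171, adjusted p = 0.156 with an estimated correlation), among them Nfkb2, the gene of the noncanonical NF-κB subunit, at 233 ± 20.4 against 77.0 ± 6.22 FPKM. The Treg list had 8 of 18 genes higher and 1 lower (10 and 3 adjusted over the list alone; adjusted p = 0.000196, adjusted p = 0.164 with an estimated correlation). Its members Ikzf2, which encodes Helios, and Nrp1, a semaphorin receptor gene, were 21.2 ± 3.86 against 1.52 ± 0.65 and 78.4 ± 13.4 against 10.3 ± 1.55 FPKM. In the IL-6 and STAT3 list 8 of 14 genes were lower and 0 higher (9 lower adjusted over the list alone; adjusted p = 2.80e-07, adjusted p = 0.0298 with an estimated correlation). Of the Th17 list 8 of 16 genes were lower and 3 higher (8 and 3 adjusted over the list alone; adjusted p = 0.00411, adjusted p = 0.156 with an estimated correlation). The Tfh list had 2 of 9 genes lower and 0 higher (2 adjusted over the list alone), namely Il21, at 0 with TNF+TGF-β, and Cxcr5, which guides cells into B cell follicles, at 12.5 ± 3.83 against 35.4 ± 5.12 FPKM. In the survival list 7 of 17 genes were higher and 0 lower (7 and 1 adjusted over the list alone), among them Bcl2l1, which encodes Bcl-xL, at 85.5 ± 1.61 against 25.8 ± 5.20 FPKM. The Tfh and survival list tests did not pass (adjusted p = 0.052 each).

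B cell markers differed between the pairs as well, with 5 of 8 lower and 0 higher with TNF+TGF-β (7 lower adjusted over the list alone; adjusted p = 0.000155, adjusted p = 0.267 with an estimated correlation). Ighm, the IgM heavy chain gene, was 394 ± 62.8 against 1059 ± 245 FPKM. Of the CD8 and NK list 3 of 5 genes were lower and 0 higher (3 lower adjusted over the list alone), with Klrd1 at 34.2 ± 4.53 against 165 ± 17.7 FPKM (adjusted p = 0.000297). Cd4, chosen after its values were seen, was 58.2 ± 19.2 against 14.5 ± 10.6 FPKM (adjusted p = 0.0199). Over all genes, 956 were higher and 719 lower with TNF+TGF-β than with IL-6+TGF-β, or 57.1% higher, and 549 and 393 differed at least 2-fold. No overlap was seen for 32.1% of genes, against 10% by chance. Ifng was 3.82 ± 2.64 against 15.8 ± 4.65 FPKM (adjusted p = 0.0186), a call lost without IL-6+TGF-β replicate 1 or 3 or TNF+TGF-β replicate 1 or 2, with an adjusted p of up to 0.0875.

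Without TNFR2, several genes that were higher with TNF+TGF-β than with IL-6+TGF-β in WT cells were low, Csf2 and Gata3 among them. Tnfrsf1b and Tbx21, also given here, were not called higher between the pairs. Tnfrsf1b itself was 3.92 ± 0.86 FPKM in Tnfr2-/- cells against 84.4 ± 20.6 in WT cells. Csf2 was 1.02 ± 0.61 FPKM in Tnfr2-/- against 77.4 ± 8.73 in WT cells (SD, n = 3 each; log2 difference −5.32 ± 0.29 (SE), adjusted p = 5.80e-07). Gata3 was 7.79 ± 3.56 against 83.2 ± 15.1 FPKM (−3.33 ± 0.30, adjusted p = 1.22e-05), and Tbx21 was 1.04 ± 0.55 against 8.18 ± 2.36 (−2.17 ± 0.25, adjusted p = 5.37e-05). Il17a and Il17f did not differ beyond the spread, with Il17a at 5.86 ± 0.75 against 4.44 ± 3.04 FPKM (adjusted p = 0.368) and Il17f at 116 ± 25.7 against 139 ± 84.6 (adjusted p = 0.998). Il10 was higher, at 1.90 ± 0.72 against 0.0867 ± 0.1172 FPKM (adjusted p = 0.000574). Ccl1, a chemokine gene, was 26.8 ± 4.70 against 1336 ± 219 FPKM, and Penk, the enkephalin precursor gene, was 7.10 ± 4.01 against 339 ± 58.4. Foxp3 was 43.9 ± 29.0 against 112 ± 17.8 FPKM (adjusted p = 0.0152), a call lost without TNF+TGF-β WT replicate 2 or the Tnfr2-/- library numbered 4 (adjusted p of up to 0.063). Il2ra was 81.2 ± 41.9 against 178 ± 25.02 FPKM (adjusted p = 0.0142), a call lost without WT replicate 3 or the library numbered 4 (up to 0.0618). Tnf was 12 ± 2.68 against 17.9 ± 2.36 FPKM (adjusted p = 0.0626), and its side of the threshold changed without Tnfr2-/- replicate 1. The B cell gene Cd79a, by contrast, was 1174 ± 486 against 92.6 ± 26.6 FPKM.

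Cell cycle genes were lower in Tnfr2-/- cells, with 26 of 28 lower and 0 higher (27 lower adjusted over the list alone; adjusted p = 4.12e-14, adjusted p = 0.287 with an estimated correlation). Plk1, a mitotic kinase gene, was 20.9 ± 9.48 against 118 ± 23.9 FPKM, and Ccna2, the cyclin A2 gene, was 34.7 ± 20.0 against 149 ± 19.5. Of the TNF superfamily list, 13 of 19 genes were lower and 1 higher (14 and 1 adjusted over the list alone; adjusted p = 2.47e-07, adjusted p = 0.287 with an estimated correlation), with Cd70 at 1.59 ± 0.38 against 44.8 ± 4.27 FPKM and Tnfsf8 at 8.71 ± 3.39 against 64.7 ± 9.09. In the Treg list 11 of 18 genes were lower and 1 higher (11 and 2 adjusted over the list alone; adjusted p = 0.00605, adjusted p = 0.409 with an estimated correlation), including Ikzf2 at 2.57 ± 0.76 against 21.2 ± 3.86 and Itgae at 79.1 ± 33.2 against 345 ± 108. The Th1 and cytotoxic list had 8 of 17 genes lower and 1 higher (8 and 1 adjusted over the list alone; adjusted p = 0.00742, adjusted p = 0.287 with an estimated correlation), with Nkg7, a cytotoxic granule gene, at 159 ± 84.6 against 946 ± 72.5 FPKM. Of the cholesterol synthesis list 9 of 19 genes were lower and 0 higher (9 adjusted over the list alone; adjusted p = 0.00605, adjusted p = 0.428 with an estimated correlation), among them Idi1, an isoprenoid enzyme gene, at 37.7 ± 10.9 against 104 ± 12.2. In the NF-κB and TNF list 8 of 20 genes were lower and 3 higher (9 and 3 adjusted over the list alone), with Nfkb2 at 62.3 ± 16.9 against 233 ± 20.4 FPKM. In the survival list 7 of 17 genes were lower and 1 higher (7 and 1 adjusted over the list alone), with Bcl2l1 at 16.8 ± 4.87 against 85.5 ± 1.61. The survival list median of −0.15 turned to 0.25, with 5 higher and 2 lower, under scaling to T cell core genes. Of the TGF-β and SMAD list 2 of 13 genes were higher and 3 lower (2 and 3 adjusted over the list alone), and the median of −0.16 turned to 0.19, with 4 higher and 1 lower, under scaling to T cell core genes. The tests of the NF-κB and TNF, the survival, and the TGF-β and SMAD lists did not pass (adjusted p = 0.0832, 0.0753 and 0.519). The B cell marker Ms4a1, which encodes CD20, stood at 161 ± 50.4 FPKM in the same Tnfr2-/- libraries against 14.9 ± 2.98 in WT. The mitochondrial ribosomal RNA gene mt-Rnr2, chosen after its values were seen, was 3269.96, 4114.64 and 9951.22 FPKM in the Tnfr2-/- libraries and at most 2379.64 in any WT library (adjusted p = 0.00228).

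The largest rises without TNFR2 included marker genes of other cells. All 8 B cell markers were higher (8 adjusted over the list alone; adjusted p = 2.47e-07, adjusted p = 0.287 with an estimated correlation), with Cd79b, the partner chain gene of Cd79a, at 1425 ± 540 against 120 ± 3.83 FPKM. In the myeloid list 10 of 13 genes were higher and 0 lower (11 higher adjusted over the list alone; adjusted p = 0.000103, adjusted p = 0.409 with an estimated correlation), with C1qa, a complement gene of macrophages, at 14.1 ± 9.15 against 0.04 ± 0.03 FPKM. Of the MHC class II and dendritic cell list 4 of 6 genes were higher and 2 lower (4 and 2 adjusted over the list alone), with H2-Ab1 at 4535 ± 1321 against 393 ± 95.9 FPKM. The test of that list did not pass (adjusted p = 0.0753). Apoe, the apolipoprotein E gene, was 4329 ± 1293 against 203 ± 33.7 FPKM, Plac8 was 706 ± 277 against 27.9 ± 1.55, and Mzb1, a plasma cell gene, was 221 ± 108 against 10.1 ± 1.01. In the erythroid list 3 of 4 genes were higher and 0 lower (4 higher adjusted over the list alone), with Hbb-bt, a beta globin gene, at 7.60 ± 6.08 against 0.483 ± 0.164 FPKM. The erythroid list test did not pass (adjusted p = 0.0668, adjusted p = 0.436 with an estimated correlation). The calls of Hba-a2 and Hbb-bs were each lost in 4 fits that left out 1 library (adjusted p of up to 0.162 and 0.115). Both were also lost without a filter and with a pseudocount of 0.1. Markers of CD8 and NK cells went the other way, with 4 of 5 lower and 0 higher (4 lower adjusted over the list alone; adjusted p = 0.000363, adjusted p = 0.287 with an estimated correlation), and Cd8a was 21.8 ± 11.5 against 173 ± 22.1 FPKM. Cd4, chosen after its values were seen, was 12.99 ± 4.03 against 58.2 ± 19.2 FPKM (adjusted p = 0.0117). S1pr1 and Id3 of the naive T cell list, which B cells also express, were 254 ± 79.3 against 31.8 ± 9.71 and 400.6 ± 104 against 67.6 ± 3.92 FPKM.

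**Figure D3:**
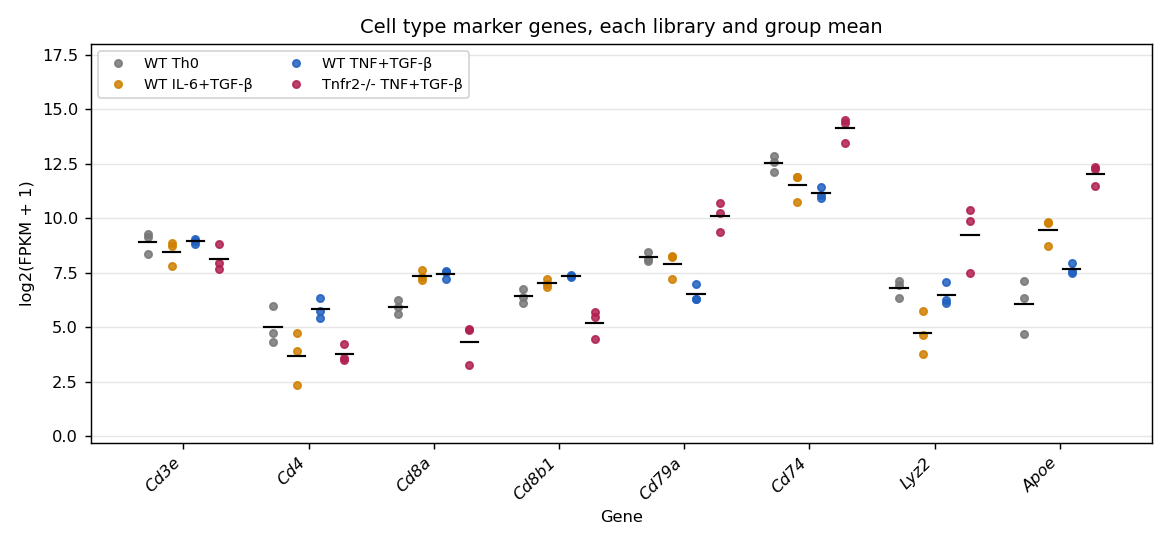
Expression of T cell, B cell and myeloid marker genes in each library, as log2(FPKM + 1), with 1 point per library, 4 groups of 3 libraries and black bars at group means. Cd79a, Cd74 and Apoe were highest in the Tnfr2-/- libraries, where Cd8a was lowest.

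Over all genes, 2608 were higher and 2290 lower in Tnfr2-/- than in WT cells, or 53.2% higher, and 1077 and 976 differed at least 2-fold. The split depended on the scaling, since rescaling to TPM gave 2103 higher and 2850 lower, or 42.5% higher, and scaling to T cell core genes gave 4948 and 1130, or 81.4%. Median-ratio scaling gave 2453 and 2543, or 49.1% higher. The median shifted by −0.111 under TPM and by 0.350 under scaling to T cell core genes. No overlap was seen for 50.8% of genes, against 10% by chance. Fbxo2, raised by TNF+TGF-β in WT cells, was 0.687 ± 0.248 FPKM in Tnfr2-/- against 81.7 ± 6.93 in WT cells, and Scin, an actin-severing protein gene, was 0.45 ± 0.11 against 47.9 ± 15.5.

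Responses to TNF+TGF-β in WT cells were compared with the change without TNFR2. Of the 2442 genes that TNF+TGF-β raised over Th0, 798 were lower in Tnfr2-/- than in WT cells, and of the 1703 it lowered, 574 were higher. Independent calls would have given 427.5 and 339.5. Csf2, Gata3, Cd70, Itgae and Fbxo2 were among the former, and Cd79a and H2-Ab1, markers of other cells, among the latter. The WT TNF+TGF-β libraries served in both comparisons, and the correlation of −0.462 across genes was no stronger than the −0.497 of simulated data without effects, although the covariance was −0.342 against −0.046 and the simulated data gave at most 1 reversed call. A further 461 genes were called in the same direction by both TNF+TGF-β and the loss of TNFR2.

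Of the 956 genes higher with TNF+TGF-β than with IL-6+TGF-β, 519 (54.3%) were lower in Tnfr2-/- cells and 67 higher, with a median log2 difference of −0.65. Cd70, Tnfsf11, Ikzf2 and Bcl2l1 were among the 519. Of the 719 genes lower with TNF+TGF-β than with IL-6+TGF-β, 318 were higher and 74 lower, with a median of 0.35. The B cell markers Cd79a, Ms4a1, Ebf1 and Ighm belonged to this class. Of 948 genes raised over Th0 by both pairs without a call between them, 217 were lower and 139 higher, with a median of −0.12. The 675 genes lowered by both, without a call between them, had 241 higher and 86 lower and a median of 0.20. These classes were chosen in part on the WT TNF+TGF-β libraries that also served as the reference. In 100 simulations without a genotype effect the class medians lay between −0.067 and −0.038, 0.04 and 0.071, −0.038 and 0.002, and −0.008 and 0.037, in the same order. These simulations let each gene vary independently, which narrows their ranges. They were extended from the first class to the others after the results had been seen.

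**Figure D4:**
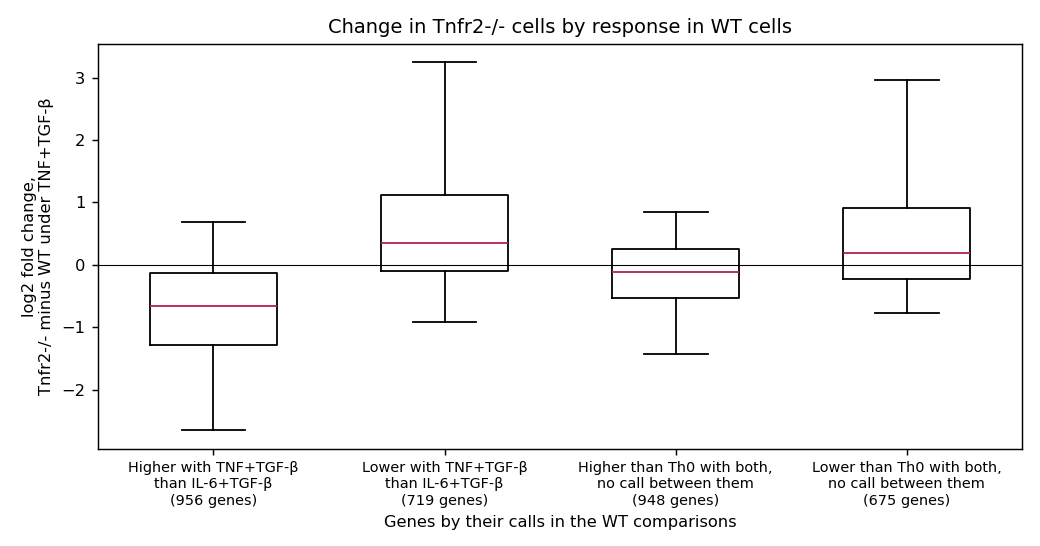
Log2 difference of Tnfr2-/- against WT cells for 4 classes of genes by their WT responses (956, 719, 948 and 675 genes), as boxes with whiskers at the 5th and 95th percentiles and red medians. The class higher with TNF+TGF-β than with IL-6+TGF-β had the lowest median, −0.65.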

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

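Among 290 genes of the fixed lists, 6 were called in opposite directions by the cytokine pairs against Th0. A difference between the pairs follows from this choice, so its size is given and its p-value is no further evidence. Csf2, which encodes GM-CSF, rose by 3.40 log2 units with TNF+TGF-β and fell by 1.90 with IL-6+TGF-β, a difference of 5.30 ± 0.29 (SE). Cd70 rose by 3.29 and fell by 1.12, a difference of 4.41 ± 0.17. Tnfsf11 rose by 2.78 and fell by 0.98 (difference 3.76), and Tnfsf8 rose by 1.16 and fell by 2.42 (difference 3.58). Ebi3, which encodes a subunit of IL-27 and IL-35, rose by 0.51 (adjusted p = 0.0385) and fell by 2.97, a difference of 3.48. Zbtb46, a transcription factor gene listed as a dendritic cell marker, rose by 1.16 and fell by 1.37, a difference of 2.53.

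For the patterns weighed here, the tests of a lower CD4 share, of FPKM scaling and of 1 aberrant library were chosen only after the result had been seen, and the other tests before. B cell markers were higher in Tnfr2-/- libraries, and a larger share of other cells in those cultures may account for it. The 18 T cell core genes had a median log2 change of −0.52, with 14 of 18 below 0, 8 called lower and 1 called higher, which is consistent with that explanation. CD8 and NK markers had a median of −2.52, which argues against a lower share of CD4 T cells that raised every other cell type alike. It does not exclude it, since these 5 genes may not follow cell share alone. In WT cells 3 of them were higher and 1 lower with TNF+TGF-β than in Th0. Median-ratio scaling left the B cell median at 3.00 but moved this comparison too little to have come out otherwise, whereas a scaling factor moves all genes of a library alike and so cannot raise B cell and lower CD8 and NK markers. Whether the cells differed through sorting, survival or growth was not tested.

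Cell cycle genes were lower in Tnfr2-/- libraries. Their median of −1.71 lay more than 1 SD (0.733) below the core median of −0.52. That was the result set beforehand against dilution of T cell RNA by RNA of other cells. It does not rule dilution out, since single core genes ran from −1.74 (Thy1) to 0.86 (Cd28). The library numbered 4 alone did not account for the fall, since the median was −1.51 without it. The other libraries were not left out for this median. Less proliferation of the T cells, a difference in RNA quality or, at least in part, dilution could give this pattern, and they were not told apart.

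Genes higher with TNF+TGF-β than with IL-6+TGF-β were lower in Tnfr2-/- cells. Dilution by other cells could account for part of it. The median of these genes, −0.65, lay within 1 SD (0.733) of the core median of −0.52. That was the result set beforehand for dilution. It does not decide the question, since the SD of single core genes is wide. The core genes Trac (0.14) and Cd247 (0.33), chosen after their values were seen, and the 948 genes raised by both pairs (median −0.12) showed no like fall. Selection on the shared WT TNF+TGF-β libraries gave no like fall in 100 simulations without a genotype effect, where the lowest median was −0.067. These simulations drew the spread of each gene independently, which narrows the range of medians. Selection among genes that vary together was therefore not excluded. Dependence on TNFR2 signalling, dilution and such selection stay open for the class, and a genotype effect without cytokines was not tested.

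The tests with regrouped libraries were all chosen before the result. Regrouping 6 libraries allows 10 splits, too few for a share under 0.05. The real split gave 2442 genes higher and 1703 lower for TNF+TGF-β against Th0, with 1 at most in any other. It gave 1844 and 1197 for IL-6+TGF-β against Th0, with 0 in any other, and 956 and 719 between the pairs, with 1 in any other. For Tnfr2-/- against WT it gave 2608 and 2290, with 5 at most in any other. Gene list calls numbered 9, 11, 9 and 11 in the same order, and another split gave as many as 11, 11, 6 and 11. Regrouping 9 libraries gave at least the 1984 shared calls in 1 of 100 splits, the real one, with 1543 as the highest other. That is the smallest share this test can give. It was under the limit of 0.05 set beforehand, which argues against chance. At least the 1372 reversed calls came up in 3 of 100 splits with the real one, and the highest other was 2384. This share met the limit of 0.05 set beforehand, and simulated data without effects gave at most 1 reversed call. As 2 other splits gave more, and the correlation was no stronger than in simulated data, chance was left open for the reversed calls. These splits were first counted with permuted group roles as different splits and then recounted with each partition once.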

How the results depend on the processing

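No gene call turned to the opposite direction under any alternative, and of 306 named gene results 286 passed in the main analysis. Scaling to T cell core genes, chosen after seeing the data, gave 4948 genes higher and 1130 lower in Tnfr2-/- against WT cells. The core genes were lower in the Tnfr2-/- libraries (median log2 change −0.52), so this scaling raised Tnfr2-/- values relative to WT. Why the core genes were lower was not tested. Tested against a 1.5-fold change, calls were 715 higher and 354 lower for TNF+TGF-β against Th0, 578 and 311 for IL-6+TGF-β against Th0, 312 and 205 between the pairs, and 718 and 568 for Tnfr2-/- against WT. The same test left 464 shared and 412 reversed calls, since it asks for larger changes. Of 40 list calls, 3 held with an estimated correlation, while fry, which does not compare a list with other genes, called 61. The Th1 and cytotoxic list between the cytokine pairs pointed down without a call in the main test (camera adjusted p = 0.997). It was called up under fry (adjusted p = 0.0177), and the cause was not tested. Without marker genes of other cells, 2392 genes were higher and 2280 lower in Tnfr2-/- cells, and without the library numbered 4 there were 2218 and 1579. The count models of the design were not run, since the values are not counts. Values below 0.125 to 0.179 FPKM rest on fewer than 3 fragments for a transcript of 1 kilobase.

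Leaving out each library in turn gave 1711 to 2221 genes higher and 1101 to 1491 lower for TNF+TGF-β against Th0, and 1341 to 2240 higher and 790 to 1638 lower for IL-6+TGF-β against Th0. It gave 654 to 859 higher and 481 to 709 lower between the pairs, and 1937 to 2602 higher and 1562 to 2667 lower for Tnfr2-/- against WT. Shared calls ranged from 1318 to 2727, reversed calls from 958 to 1599, named gene calls from 263 to 284 and list calls from 36 to 44. The counts lower against Th0 for TNF+TGF-β were 1111 and 1106 without Th0 replicates 1 and 3 and 1101 without TNF+TGF-β replicate 2, and for IL-6+TGF-β 790 without Th0 replicate 3. Fewer samples give less power, and the cause of the remaining difference between libraries was not tested.

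The replicate numbers do not pair the samples. Of 15 pairs of libraries with the same number, 5 had correlations of residuals over 0.1 (−0.284 to 0.344), and 6 of 12 libraries matched best with their own number. A block for replicate number gave 1900 genes higher and 1353 lower in Tnfr2-/- cells, where the library numbered 4 formed a block of its own, so that this comparison rested on 2 pairs. With the block, the calls of Foxp3 (−0.97, adjusted p = 0.119) and Il2ra (−0.83, adjusted p = 0.123) in Tnfr2-/- cells were lost.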

Other observations

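In cells labelled CD4 T cells, Cd8a and Cd8b1 were both above Cd4 in 11 of 12 libraries, and the ratio of Cd8a to Cd4 ran from 0.828 to 47.7. Cd4 and Igha here were chosen after their values were seen. In Th0 libraries Cd8a was 60.5 ± 12.9 FPKM and Cd4 35.6 ± 23.5 (SD, n = 3), with IL-6+TGF-β Cd8a was 165 ± 26.4 and Cd4 14.5 ± 10.6. The T cell receptor constant gene Trac was 872.9 ± 22.2 FPKM with TNF+TGF-β in WT and 974.6 ± 196 in Tnfr2-/- cells (adjusted p = 0.463). Igha, the constant region gene of immunoglobulin A, was 0.54 ± 0.48 FPKM in Th0, 140.3 ± 23.9 with IL-6+TGF-β and 74.7 ± 16.8 with TNF+TGF-β (adjusted p = 1.19e-07 and 4.19e-07 against Th0). In Tnfr2-/- cells Igha was 35.7 ± 17.5 FPKM while Cd79a was 1174 ± 486.

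Snord13, a small nucleolar RNA gene, was listed at 0 in all Th0 and Tnfr2-/- libraries. In WT cells it averaged 178 FPKM with IL-6+TGF-β and 58.8 with TNF+TGF-β. FPKM are scaled by transcript length, so for so small an RNA these averages may rest on few fragments. Depth was estimated from transcripts of 800 to 3000 bases, and no fragment limit was worked out for shorter ones. Whether the difference from 0 reflects expression was therefore not tested. The mitochondrial ribosomal RNA gene mt-Rnr1, also chosen after its values were seen, was higher in Tnfr2-/- than in WT cells under TNF+TGF-β (log2 difference 1.52, adjusted p = 0.0149).

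For some lists the median and the mean differed in sign. In TNF+TGF-β against Th0 the survival list had a median of −0.17 and a mean of 0.15, and its test pointed up. In IL-6+TGF-β against Th0 the TNF superfamily list had 0.10 and −0.02 and the cell cycle list 0.04 and −0.06, with both tests pointing down. Between the pairs the MHC class II and dendritic cell list had −0.60 and 0.09. In Tnfr2-/- against WT the coinhibitory receptors had 0.24 and −0.12, and the AP-1 and stress list −0.19 and 0.05, where scaling to T cell core genes turned the median to 0.21. None of the list tests in this paragraph passed, and their lowest adjusted p was 0.459.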
